A study of Homo sapiens with 5 samples.

How the data were processed

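Gene expression was measured by RNA sequencing in 5 libraries of Ishikawa cells, an established human endometrial carcinoma line. Cells in 3 libraries carried a lentiviral short hairpin RNA (shRNA) directed at the long non-coding RNA LINC00958 (sh-LINC00958), and cells in 2 libraries carried a negative control (sh-NC). Per the labels' protocols, puromycin at 2.5 µg/ml was applied 72 h after infection, total RNA was treated with DNase, and 1 µg per sample entered an mRNA library kit. The number and the sequences of the hairpins, the time of harvest and the strand setting are not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

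The values are TPM, a measure of transcript abundance scaled for gene length, deposited by the authors as 1 table of 58174 genes with 1 column per library. The submitters' processing notes name FastQC 0.11.2, Trimmomatic 0.36, HISAT2 2.0 and StringTie 1.3.3b with GRCh38, and no annotation release. TPM divides reads by gene length and scales every library to the same total of about 1000000, so the sequencing depth is unknown and no counting interval or floor can be given. It also makes every value relative to the other RNAs of its library. Of the listed gene IDs, 57836 were found in GENCODE release 29, which supplied coordinates, biotypes, transcript GC content and exon length, and 53551 carried the same symbol there. No pair of libraries held identical values.

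The comparison was computed on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend). The filter was a mean TPM of at least 1 over the 5 libraries, which left 17049 genes, and the libraries were not scaled further. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All adjusted p-values of single genes below come from this fit unless another is named. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. In simulated data with known changes among these 17049 genes, the fit recovered 33% of genes changed by 1 on the log2 scale and 4% of genes changed by 0.585, and 2 of its 39 calls were false. Only 200 genes were changed in that simulation, against 1671 called in the data. The adjusted threshold depends on the share of changed genes, so these rates do not carry over to the comparison itself. Genes that did not pass are still not shown to be unchanged.

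The gene lists, 33 in all, were fixed before the data were examined: study partners, LINC00958 neighbours, E2F targets, G2/M mitosis, cell cycle inhibitors and p53 targets, apoptosis, mesenchymal genes, epithelial genes, estrogen response, interferon response, NF-kB and inflammatory genes, immediate early genes, unfolded protein and ATF4 response, heat shock genes, hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal protein genes, replication-dependent histones, YAP-TEAD targets, Wnt targets, TGF-beta targets, matrix proteases and invasion, endometrial differentiation, m6A and RNA-binding regulators, small RNA machinery, and markers of fibroblasts, blood cells, endothelial cells, kidney line and neural cells, and squamous cells. The 32 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. On simulated values, drawn independently for every gene, camera called only the list that had been shifted. Such values hold no correlation within lists, so they do not test the preset correlation. In the data the estimated correlation was 0.22 for the mitosis list and 0.52 for the ribosomal protein list. A list can lose evidence in that test without correlated members. For YAP-TEAD targets, with an estimated correlation of -0.026, the unadjusted camera p went from 0.0462 to 0.116. A call lost there is therefore not shown to come from correlation.

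The rule for named genes was also fixed beforehand. It takes LINC00958, the study partners, the 3 members of each list with the smallest p, and in each direction the 12 genes with the largest fitted change among those past the threshold. The latter needed groups that did not overlap, a mean TPM of at least 5 in the higher group and a symbol that is not a clone name. Other list members past the threshold are named to account for counts, and a few genes that the rule takes are not reported here. A few others are marked where they were chosen after their values were seen.

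The alternatives planned beforehand were pseudocounts of 0.1 and 5, no filter, a mean TPM of at least 5, median-ratio scaling, quantile normalization, rescaling without mitochondrial and the 10 most abundant genes, limma without the trend, robust eBayes, library quality weights, a minimum log2 change of 1, the replicate number as a block, and each library left out in turn. After the data were examined, a fit on genes of 200 nt or more was added. A second addition removed a smooth trend of GC content and exon length from every library. Where that trend differs between the groups, its removal also takes out a true change that follows GC content or length. A call lost in this way is therefore not shown to be false. Sequence heptamers of 3' UTRs, blocks of neighbouring genes and short genes were examined with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with Matplotlib 3.10.9. The limma fit, camera, the GC and length correction, the block scan and the heptamer scan were tested on simulated or shuffled values with a known change put in, and the comparison of short genes was not.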

Results

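The data comprised TPM values from 5 RNA sequencing libraries of Ishikawa cells, 3 of sh-LINC00958 and 2 of sh-NC. The comparison asked which transcripts change when LINC00958 is silenced. Between 27896 and 29411 genes had a value above 0 per library. Mitochondrial genes took 12.9% to 14.97% of TPM and ribosomal protein genes 11.5% to 13.3%.

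LINC00958 was present at 50.04% of its control level in cells carrying the hairpin. The gene (ENSG00000251381, a lincRNA on the minus strand of GRCh38 chromosome 11, 12961842 to 12989548) measured 67.2, 67.1 and 58.4 TPM in the sh-LINC00958 libraries and 119.3 and 137.4 TPM in the sh-NC libraries. The means were 64.2 ± 5.05 TPM (SD, n = 3) and 128.4 ± 12.8 TPM (SD, n = 2). The log2 fold change was -0.99 with a standard error of 0.106 (95% interval -1.25 to -0.73, limma adjusted p = 0.0119). An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 2 allow. The limma adjusted p rose above the threshold without sh-LINC00958 replicate 1 (0.0545), sh-NC replicate 1 (0.0677) or sh-NC replicate 2 (0.0871), while the LINC00958 log2 fold change stayed between -0.89 and -1.09.

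**Figure D1:**
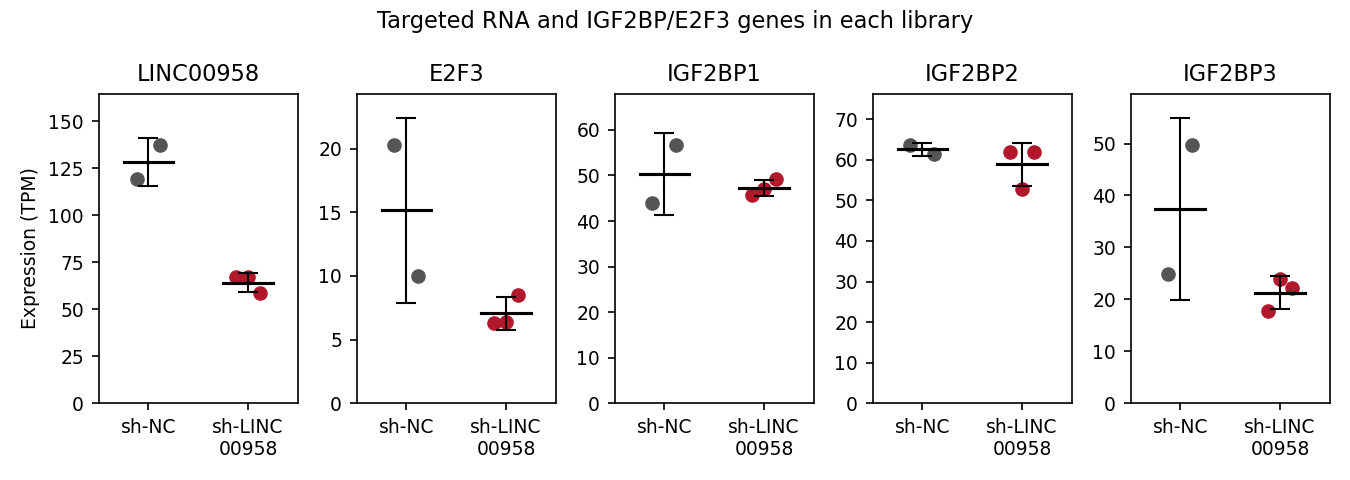
Expression in TPM (vertical axis, from 0) of LINC00958, E2F3 and the IGF2BP genes in each library, with points for libraries, wide bars for means and error bars for SD (sh-NC, n = 2; sh-LINC00958, n = 3). LINC00958 lay between 58.4 and 67.2 TPM under sh-LINC00958 and at 119.3 and 137.4 TPM under sh-NC.

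The study's authors are known to have linked LINC00958 to the transcription factor E2F3 and to IGF2BP3, a reader of N6-methyladenosine, and none of the 4 study partners passed the test. E2F3 averaged 7.05 ± 1.27 TPM (SD, n = 3) against 15.2 ± 7.26 TPM (SD, n = 2), a log2 fold change of -0.94 (95% interval -1.66 to -0.21, limma adjusted p = 0.0985). IGF2BP3 averaged 21.3 ± 3.14 against 37.3 ± 17.5 TPM (log2 fold change -0.71, 95% interval -1.43 to 0.0027, limma adjusted p = 0.164). The control libraries set these values. The E2F3 log2 fold change was -0.46 without sh-NC replicate 1 and -1.41 without sh-NC replicate 2, and the IGF2BP3 log2 fold change was -1.20 and -0.23. IGF2BP1 and IGF2BP2 had log2 fold changes of -0.08 (95% interval -0.38 to 0.23) and -0.09 (95% interval -0.34 to 0.16). The list as a set gave a camera adjusted p of 0.380, and 0 members passed when adjusted over the list alone (1, E2F3, at an unadjusted p under 0.05).

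Across the transcriptome, 702 genes were higher and 969 lower in sh-LINC00958 at an adjusted p of 0.05. At least a 2-fold fitted change was seen in 96 and 152 of them. Among protein-coding genes with large rises were PLAU, the urokinase protease, at 23.4 ± 6.66 against 6.52 ± 1.94 TPM, and FOSL1, an AP-1 subunit, at 25.8 ± 6.12 against 8.01 ± 2.52 TPM (SD, n = 3 and 2 here and below). STX16, a trans-Golgi syntaxin (log2 fold change 1.65 ± 0.105, SE), and NIPSNAP1, a mitochondrial protein gene (1.63 ± 0.0806), rose as well. Large falls included CLDN4, a tight junction claudin (-2.54 ± 0.480), FBXO34 (-2.51 ± 0.260), the GTPase gene NRAS (-1.73 ± 0.147), the clamp loader subunit RFC3 (-1.66 ± 0.1097), the acetyltransferase gene NAA50 (-1.64 ± 0.0942) and CCDC39 (-1.57 ± 0.206). The control libraries differed for CLDN4, with a mean of 28.8 ± 22.6 TPM, and its call was lost in the fit without a trend (adjusted p = 0.0536).

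Of the genes with the largest fitted rises, SNORD5, SNORD12 and SNORA77B are small nucleolar RNAs of 73, 90 and 125 nt. SNORD5 had 24.9 ± 7.69 against 0.445 ± 0.0303 TPM and SNORD12 had 20.3 ± 1.16 against 0.284 ± 0.0212 TPM. SNHG25, ZNF702P and C22orf34, non-coding transcripts, rose with log2 fold changes of 2.01, 1.81 and 1.66. MIR222HG, the host transcript of miR-221 and miR-222, was listed at 0 in both sh-NC libraries and measured 4.51, 6.16 and 5.60 TPM in sh-LINC00958. Among the falls were MIR3658 (56 nt, log2 fold change -6.30), SNORD27 (72 nt, -4.76), hsa-mir-548d-1 (97 nt, -2.22) and RNU6-583P (92 nt, -2.11). Over all 597 tested genes under 200 nt, called or not, the within-group SD had a median of 2.02 times that of longer genes at the same level. Whether the values of such genes reflect the small RNAs themselves is not shown. PPAN-P2RY11 (2.04) and BIVM-ERCC5 (-1.80) are read-through annotations that share exons with their component genes, so their values are uncertain. After removal of the GC and length trend BIVM-ERCC5 (-1.71, adjusted p = 0.0751) and hsa-mir-548d-1 (-1.74, adjusted p = 0.0524) were not called. PPAN, P2RY11, BIVM and ERCC5, looked up after these values were seen, had adjusted p-values of 0.761, 0.936, 0.261 and 0.731.

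Genes of mitotic entry and chromosome segregation were lower as a group. Of 30 measured members of the G2/M mitosis list, 10 fell, 1 rose (CENPA) and 19 did not pass, and 18 fell and 1 rose when adjusted over the list alone. CDK1, the mitotic cyclin-dependent kinase, went from 280.5 ± 17.5 to 117.8 ± 14.5 TPM (log2 fold change -1.25 ± 0.117, SE), and its cyclin partner CCNA2 from 173.9 ± 10.2 to 96.9 ± 7.89 TPM. ANLN (-0.86), NUSAP1 (-0.89), CENPE, HMMR, KIF11, TOP2A, KIF23 and CCNB1 (-0.31) also fell. The list's camera adjusted p was 5.0e-07 at the preset correlation. It was not called with an estimated correlation (camera unadjusted p = 0.0998, adjusted p = 0.893) or with fry (unadjusted p = 0.0063, adjusted p = 0.0791). The E2F targets list gave 5 falls (RFC3, E2F7, CCNE2, CCNE1 and GINS1) and 1 rise (E2F1, log2 fold change 0.35) among 38 measured members, the same counts adjusted over the list alone, with a camera adjusted p of 0.461. Among 24 measured cell cycle inhibitors and p53 targets, 3 fell and 0 rose (3 and 1 adjusted over the list alone). Those that fell were ZMAT3 (-1.05), RRM2B and CDKN1B, which encodes the CDK inhibitor p27 (-0.67). After removal of the GC and length trend, 10 mitosis genes were called lower, 7 of them among the original 10 (CDK1, ANLN, CCNA2, KIF23, TOP2A, KIF11 and NUSAP1). RFC3, E2F7, CCNE1, GINS1, ZMAT3 and CDKN1B kept their calls, and CCNE2, E2F1 and RRM2B lost theirs with smaller folds (-0.61, 0.17 and -0.29 after the removal). CENPA was not called either, although its fold barely moved (0.39 before and 0.36 after).

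**Figure D2:**
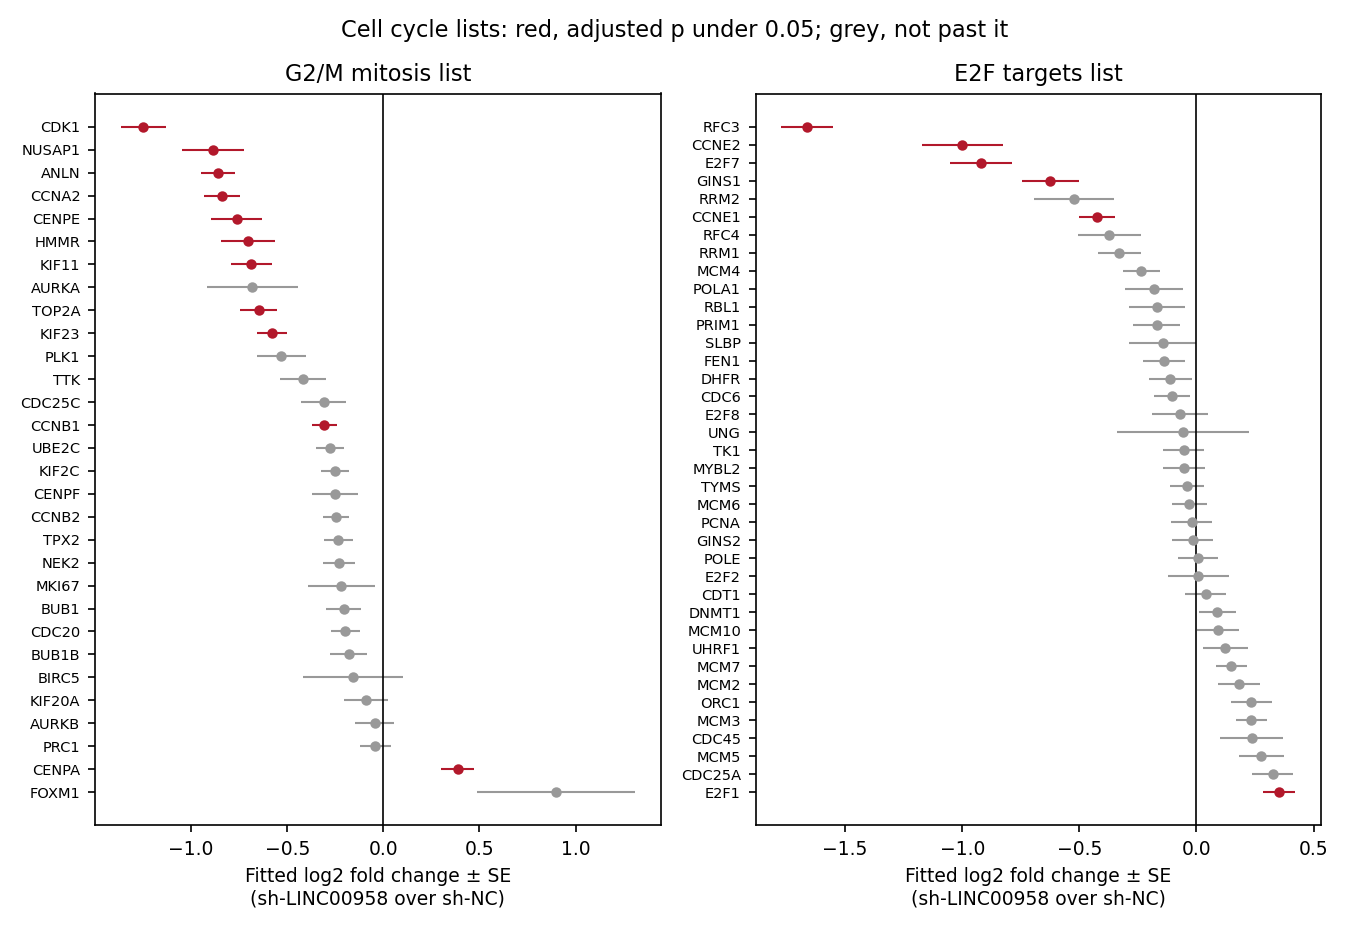
Fitted log2 fold change (horizontal axis, sh-LINC00958 over sh-NC, 3 and 2 libraries) with standard error bars for every measured gene of the mitosis list (left, 30 genes) and the E2F targets list (right, 38 genes), red where the limma adjusted p was under 0.05. In the mitosis list 28 of 30 points lie below 0, and in the E2F list 24 of 38.

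Immediate early genes, which respond to growth factors, stress and cell handling, included 5 that rose and 2 that fell among 25 measured (7 and 2 adjusted over the list alone). The AP-1 genes FOS (log2 fold change 1.16 ± 0.1002, SE), JUN (1.31 ± 0.161), FOSL1 and JUND and the early response gene IER3 (0.84) rose. The MAP kinase pathway inhibitors SPRY4 (-0.49) and DUSP4 (-0.69) fell. Among 22 measured YAP-TEAD targets 2 rose, the matricellular gene CYR61 (1.11 ± 0.108) and WWC1 (0.44), and 0 fell, with the same counts adjusted over the list alone. In the NF-kB list NFKB2 (0.49) alone of 17 members rose (2 adjusted over the list alone). Wnt targets had 1 rise (CD44, 0.82) and 2 falls (CCND1 and SOX9) among 19, and TGF-beta targets 1 rise (SKI, 0.38) and 2 falls (BMPR2, -0.88, and SKIL, -1.28) among 25. Adjusted over the list alone these were 1 and 2 for Wnt targets and 2 and 2 for TGF-beta targets. Estrogen response genes had 2 rises (SIAH2 and ADCY9) and 1 fall, that of CCND1, which encodes cyclin D1 (420.8 ± 25.4 against 702.1 ± 6.77 TPM), among 20 (4 and 3 adjusted over the list alone). Camera adjusted p-values of these lists were 0.380, 0.369, 0.587, 0.720, 0.720 and 0.790 in the order given. After removal of the GC and length trend JUND, NFKB2, WWC1, SKI, SKIL, BMPR2, SIAH2 and ADCY9 had smaller folds and were no longer called. CD44 was not called either (adjusted p = 0.0516), but its fold did not shrink (0.82 before and 0.86 after).

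Adhesion and invasion genes moved in both directions. Among 30 epithelial genes PKP3 (log2 fold change 0.56), KRT18 (0.44) and CLDN7 (0.49) rose and CLDN4 and the desmosomal cadherin DSG2 (-0.49) fell, with 4 rises and 4 falls adjusted over the list alone. Among 18 mesenchymal genes the collagen cross-linking enzyme LOX (-0.84) fell and 0 rose (1 and 2 adjusted over the list alone). Of 16 matrix protease and invasion genes PLAU and MMP15 (0.41) rose, and the membrane sheddases ADAM17 (-0.60), ADAM10 (-0.56) and ADAM9 (-0.36) fell, with the same counts adjusted over the list alone. Camera adjusted p-values were 0.461, 0.720 and 0.720. When the GC and length trend was removed, PKP3, KRT18, CLDN4 and PLAU kept their calls and the other genes named here lost theirs, each with a smaller fold.

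Lipid and sugar metabolism genes also split. MSMO1, a sterol demethylation enzyme, fell from 312.4 ± 9.44 to 141.4 ± 15.4 TPM (log2 fold change -1.14 ± 0.104, SE), STARD4 (-0.78) and IDI1 (-0.78) fell, and PMVK (0.67) rose, among 25 cholesterol synthesis genes (3 rises and 6 falls adjusted over the list alone). Of 23 fatty acid synthesis genes ELOVL7 (-0.79), ACLY (-0.42), FADS1 (-0.44) and ACSL3 (-0.47) fell and ME1 (0.66) rose (7 and 2 adjusted over the list alone). Among 33 hypoxia and glycolysis genes the glucose transporter gene SLC2A1 (418.3 ± 25.03 against 647.1 ± 1.02 TPM), the hexokinase gene HK2 (-0.76) and BNIP3L fell, while PFKL (0.88), PFKFB3 (0.67) and HK1 (0.36) rose (3 falls and 5 rises adjusted over the list alone). Oxidative phosphorylation genes had 3 rises, NDUFA8 and NDUFS8 among them, and 1 fall (NDUFV2) among 40, the same adjusted over the list alone. Camera adjusted p-values were 0.461, 0.380, 0.718 and 0.213. MSMO1, IDI1, ACLY, FADS1, ME1, HK2, SLC2A1, PFKL and NDUFA8 kept their calls after removal of the GC and length trend, and the other genes named here lost theirs, each with a smaller fold. Without sh-LINC00958 replicate 2 the list oxidative phosphorylation was called higher at the preset correlation (camera adjusted p = 0.0231). With all libraries its adjusted p was 0.893 with an estimated correlation and 0.270 with fry.

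In the unfolded protein and ATF4 list, 5 of 34 genes rose (PPP1R15A, 0.66; TRIB3, 0.79; CRELD2, PHGDH and CALR) and 3 fell (the cystine transporter gene SLC7A11, -1.05 ± 0.0995, SE, with VLDLR and EDEM1). These were 8 and 4 adjusted over the list alone. The heat shock list had 1 rise (HSPA1B, 0.38) and 1 fall (CHORDC1, -0.93) among 19 (3 and 1 adjusted over the list alone). Apoptosis regulators had 3 rises, BCL2L1 (0.73) and FADD among them, and 1 fall among 22 (3 and 2 adjusted over the list alone). Camera adjusted p-values were 0.380, 0.461 and 0.853. CRELD2, PHGDH, CALR, HSPA1B, BCL2L1 and FADD had smaller folds after removal of the GC and length trend and lost their calls. None of 24 interferon response genes passed in limma, over all genes or adjusted over the list alone, and 1 of them, BST2, had an unadjusted p under 0.05 (adjusted p = 0.0621). The camera adjusted p of that list was 0.464.

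Ribosomal protein genes stood slightly higher as a group, with a median log2 fold change of 0.13 over 77 genes and a camera adjusted p of 0.0017. That call was lost with an estimated correlation (camera unadjusted p = 0.479, adjusted p = 0.893) and with fry (unadjusted p = 0.212, adjusted p = 0.339). For the list ribosomal protein genes it was also lost with quantile normalization (adjusted p = 0.263) and without sh-LINC00958 replicate 1 (adjusted p = 0.0541). RPL11 (0.40) alone rose, and 0 passed adjusted over the list alone, but 25 of the 77 rose without sh-LINC00958 replicate 2. That library had 11.7% of its TPM in ribosomal protein genes, against 13.3% and 12.9% in replicates 1 and 3 and 11.5% and 11.6% in sh-NC. After removal of the GC and length trend the list was still called (camera adjusted p = 0.0137) and RPL11 was not (adjusted p = 0.0564), at a log2 fold change of 0.42. Genes of small RNA processing included 2 falls among 13, AGO2 (-0.42) and DICER1 (-0.74; -0.47 and not called after that removal), the same adjusted over the list alone (camera adjusted p = 0.380). Of 19 m6A regulators RBM15B (0.64) and YTHDF2 (0.38) rose (2 rises and 1 fall adjusted over the list alone; camera adjusted p = 0.790). Near LINC00958, MICAL2 (0.89) rose and FAR1 (-0.76) fell among 13 neighbours (2 and 1 adjusted over the list alone, camera adjusted p = 0.790), and neither was called after removal of the GC and length trend. The fold of FAR1 shrank to -0.18, while that of MICAL2 was 0.81 (adjusted p = 0.0843).

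No member passed the limma test, over all genes or adjusted over the list alone, among 13 mitochondrially encoded genes, 18 replication-dependent histones, 17 endometrial differentiation genes, 6 blood cell, 6 endothelial and 7 kidney line and neural markers. At an unadjusted p under 0.05 there were 1, 3, 4, 0, 1 and 3 in the order given, and camera adjusted p-values were 0.587, 0.948, 0.790, 0.645, 0.720 and 0.790. HOXA10, a regulator of endometrial differentiation, had the smallest p of its list (log2 fold change -1.52, adjusted p = 0.0568). After removal of the GC and length trend 2 genes of that list were called lower, PAX8 (-0.39, adjusted p = 0.0265) and SOX17 (-0.43, adjusted p = 0.0487). Of 3 squamous markers measured none passed over all genes and 1, SFN, did adjusted over the list alone (camera adjusted p = 0.380). Only 1 fibroblast marker was measured, so that list was not tested. The median, mean and camera test of a list differed in sign for p53 targets, apoptosis, epithelial, endometrial and histone genes, and fry alone differed for m6A genes. No direction is given for these lists.

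GC content separated the groups too. Tested genes were put in 4 bins of like size by transcript GC content. In the bin with the lowest content (23.1% to 42.0%) the median log2 fold change was -0.29, with 664 genes called lower and 46 higher. In the bin with the highest (56.0% to 86.4%) it was 0.18, with 30 lower and 353 higher. GC content and length accounted for 20.97% of the variance of the fold changes. Once their trend was removed, 432 genes were higher and 474 lower, of which 325 and 403 were among the original calls, and LINC00958 (-0.96, adjusted p = 0.01001) and the mitosis list (camera adjusted p = 3.1e-07 at the preset correlation) were still called, as was the ribosomal protein list (camera adjusted p = 0.0137). Before the removal neither list was called with an estimated correlation (adjusted p = 0.893 for both, camera unadjusted p = 0.0998 and 0.479) or with fry (adjusted p = 0.0791 and 0.339). For the 44 list members that lost a call, the fold afterwards was a median of 61.6% of its size before, and for 5, CENPA, CD44, RPL11 and MICAL2 among them, it was at least 90%.

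**Figure D3:**
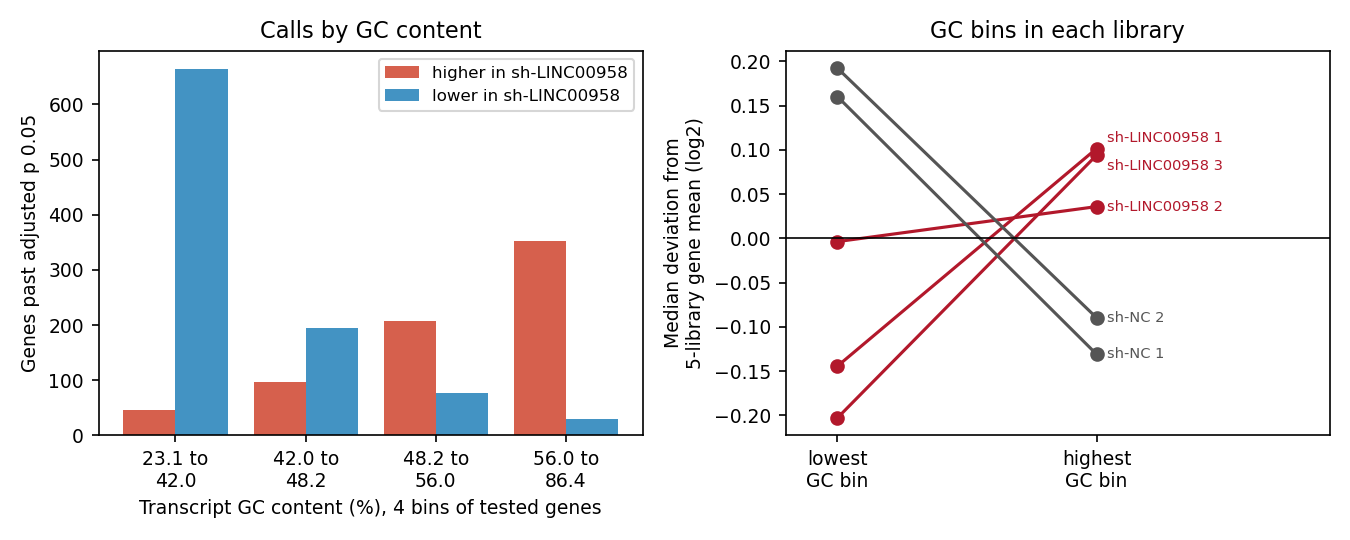
Left, number of genes past adjusted p 0.05 in each of 4 bins of transcript GC content (horizontal axis, percent), red for higher and blue for lower in sh-LINC00958. Right, median log2 deviation from the 5-library gene mean in the lowest and the highest GC bin, with 1 line per library (red, sh-LINC00958; grey, sh-NC); the lowest bin lay at 0.16 and 0.19 in sh-NC and at -0.14, -0.0037 and -0.20 in sh-LINC00958.

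The first principal component (51.1% of variance) parted the groups, with sh-LINC00958 replicate 2 the nearest of its group to sh-NC. Tested genes with non-overlapping groups made up 49.9%, against 20% by chance. The numbers of calls rested on single libraries, with 36 higher and 51 lower without sh-LINC00958 replicate 1, 904 and 1486 without replicate 2, 112 and 145 without replicate 3, 21 and 12 without sh-NC replicate 1, and 10 and 6 without sh-NC replicate 2. In these fits mitosis genes lay below 0 in 24 to 28 of 30 cases, but none was called lower without sh-LINC00958 replicate 1, sh-NC replicate 1 or sh-NC replicate 2.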

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

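Tests on genes of 200 nt or more and with the GC and length trend removed were chosen after the data were seen. Calls (1671) kept their sign in every planned fit that tested them. They were selected in the same libraries, so this says little about whether they would recur. Counts of genes higher and lower moved by over 1.5 times with a minimum log2 change of 1 (96 and 152, fewer by construction), no filter (207 and 269), limma without the trend (371 and 518), library quality weights (1428 and 1851), and the GC and length trend removed (432 and 474). With the replicate number as a block, 0 genes were higher and 2 lower in limma (4213 at an unadjusted p under 0.05), and LINC00958 gave -0.92 (adjusted p = 0.104). That fit leaves 1 residual degree of freedom. No sh-NC library shares the number of sh-LINC00958 replicate 3, so the fold changes of that fit rest on 2 libraries of each group. Deviations of same-numbered libraries correlated at 0.0013 and 0.050. With 2 sh-NC libraries both values rest on the same control difference. No pairing was seen, but a weak one cannot be excluded. Leaving out 1 library gave 10 to 904 genes higher, 6 to 1486 lower, the LINC00958 log2 fold change at -0.89 to -1.09 and 1 to 3 lists called. A lone control library is there assumed to vary like the other group. Of 2 lists called, 1 was called with quantile normalization, 0 with an estimated correlation and 0 with fry. Reversed values, none past the threshold, were the IGF2BP1 log2 fold change (0.105) and the HBA1 log2 fold change (-0.033) without sh-NC replicate 2 (ranges over libraries left out, -0.26 to 0.105 and -0.033 to 0.20), and HBA1 (-0.072) and the YTHDC2 log2 fold change (0.076) with the GC and length trend removed. Beyond the fewer samples, genes or degrees of freedom named, the cause was not tested. Depth is unknown, so its limits could not be assessed.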

Other observations

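Several tests were chosen only after the results were seen. They are the heptamer tests of TCGGAGA, the count of lower calls that held after the GC correction and the condition on zinc finger genes. The shuffle among those genes and the allowance for spread in the microRNA test were also chosen then. The other tests of explanations had their bounds fixed before those tests were run. The patterns they address, such as the rise of MIR222HG, came from the fit of the same data.

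Several genes outside the named lists, chosen after their values were seen, changed by a large amount at high abundance. TPM4, a tropomyosin of the actin cytoskeleton, measured 513.1 ± 27.4 TPM (SD, n = 3) against 175.0 ± 14.1 TPM (SD, n = 2), a log2 fold change of 1.55 (limma adjusted p = 0.0042). FZD6, a Wnt receptor, measured 34.7 ± 3.27 against 100.5 ± 0.542 TPM (-1.51), and GOLGA2, a Golgi matrix protein gene, 168.7 ± 13.4 against 62.9 ± 18.7 TPM (1.44). All 3 were still called after removal of the GC and length trend.

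Genes lower in sh-LINC00958 were mostly poor in GC. A GC or length bias of the libraries may account for part of them. After the trend was removed 43.6% of all called genes were kept, under the bound of 50% set before that test. The test cannot tell such a bias from a true change of GC-poor genes, because the trend ran along the groups. In the lowest GC bin the deviation was 0.16 and 0.19 in sh-NC and -0.14, -0.0037 and -0.20 in sh-LINC00958. The 563 lower genes that lost their call went from a median log2 fold change of -0.64 (median SE 0.124) to -0.33 (0.0944), so as a set their calls ended with a smaller fold. The trend as fitted does not account for the 403 lower calls that held, with medians of -0.78 before and -0.65 after. A GC or length bias that the smooth fit did not capture could remain in them. Silencing by the seed of the hairpin guide stays open, as does an effect of LINC00958 loss. The lowest 3' UTR heptamer found in LINC00958, TGGCCAC, had a z of -4.05, between the bounds of -6 and -4. The lowest of all (z = -5.04) does not occur in it. Carriers of TGGCCAC lay only 0.035 lower after adjustment, and 119 of 1773 were called lower, against 860 of all 12687 protein-coding genes tested. For CTATTGA, also in LINC00958 (z = -3.67), 172 of 1060 carriers were called lower. The hairpin sequence is unknown, so neither need be its seed site.

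Short RNA genes held 7 of the 20 largest called changes. Unstable estimates for genes under 200 nt are a candidate explanation in general. Their within-group SD was a median of 2.02 times that of longer genes of like level, above the bound of 1.5. That ratio covers all 597 short genes tested, of which 6.7% were called, against 9.9% of longer genes. The largest changes had standard errors far below their folds (MIR3658 0.127, SNORD27 0.188, SNORD5 0.264, SNORD12 0.124). Within-group spread, which may be technical, does not account for those genes. That does not establish a change of the small RNAs themselves. The libraries came from an mRNA kit, and how reads were assigned to genes this short is not known. Reads of the surrounding gene may contribute to part of the short gene changes. Of called short genes inside another gene, 72.7% (24 of 33) went in its direction, past the bound of 70%. The exact 95% interval of 54.5% to 86.7% spans that bound. The median absolute log2 fold change was 1.25 for called short genes and 0.31 for the genes around them, 10 of which were called, but short genes enter that set by passing the test, so the sizes do not decide it. MIR3658 (in UCK2, 0.22), SNORD5 (in TAF1D, -0.68) and SNORD12 (in ZFAS1, -0.34) went against the gene around them.

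Genes with TCGGAGA in the 3' UTR tended to be higher in sh-LINC00958 (z = 6.26 as fitted; 6.11 with the GC and length trend removed, which argues against that trend; and 6.15, rank 2 of 15896 heptamers, without zinc finger genes too). TCGGAGA and CGGAGAA (z = 5.95) are complementary to the start of TTCTCCGAACGTGTCACGT, a commercial non-targeting sequence recalled after these heptamers were seen; that sh-NC carried it is not stated in the sources used here. Silencing of such genes in sh-NC is a hypothesis that could produce this, and carriers in the 3' UTR (mean 0.131) exceeded carriers in the coding part alone by 0.061 (SE 0.020), with 0.24 (71 genes) for the octamer TCGGAGAA against 0.13 and 0.10 for either heptamer alone (0.118 above the higher, SE 0.059). Against it stand that carriers in the coding part alone also lay above 0 (0.071, SE 0.0080, against -0.018 for genes with neither), that the matching strand is the one written as the target, while sites of its complement had z of 1.38 and -0.023, and that GGAGAAA (6.53), AGGAGAA (5.03) and TGGAGAA (4.84), which match less of it, also ranked high. Coding-part carriers were not adjusted for coding length, and the idea was found and tested on the same data over 3 passes of all heptamers.

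Carriers of the seed site of miR-221 and miR-222 (1120 genes) had a z of -0.50 and an adjusted mean difference of -0.0058. The bound set before that test counted a z above -1 against a lowering of their targets. The margin was less than the SD of z over heptamers (1.11), an allowance added after the value was seen. With that allowance, whether the rise of MIR222HG lowered its targets was not decided. The largest median of 25 neighbouring genes was 0.55 on chromosome 19 (52297177 to 53496255) after the GC correction, above the highest of 1000 shuffles (0.37), which met the bound set for a copy number difference. As fitted, the median of the same genes was 0.30, under the 95th percentile of the shuffles (0.41), so the block passes that bound only after the correction. All 25 are zinc finger genes. Of the 14 blocks past that shuffle, 13 overlap there and 1 lies in another stretch of chromosome 19 (20535825 to 23758891). The corrected median was 0.18 over the 220 zinc finger genes of chromosome 19 outside the block and 0.097 over 264 on other chromosomes. With values shuffled among the 245 of chromosome 19, the block lay above the 95th percentile of the largest medians (0.46) and below the highest (0.605), so position and gene family cannot be told apart. Among blocks as fitted, the largest was -0.61 on chromosome 3 (170037929 to 180870933, highest shuffle 0.53), and that block's median was -0.25 after the correction. As fitted, 11 of its 25 genes fell and 0 rose. SKIL, ZMAT3 and CCDC39, named above, are among those that fell, so their falls may not be independent of one another.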
